A study of Solanum lycopersicum with 8 samples.

How the data were processed

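Total RNA from breaker-stage fruit of tomato (Solanum lycopersicum), cultivar Micro-Tom, was labelled with Cy3 and hybridised to 1-colour Agilent arrays, per the labels. Groups were taken from the labels' genotype and line, which gave 4 groups of 2 samples: wild-type and knockdown progeny of line 1-10, and of line 1-30. One array was run per sample, 8 in all, and none was left out. The spot intensity of each array was made with Agilent Feature Extraction 10.5.1.1, per the file headers, which subtracted the background and detrended the signal within the array and put surrogate values on dim spots. The submitters' processing notes name the same program without a version. The deposited value table of the series holds log2 intensities. Sorted, its columns differ by at most 0.000934, so the authors had quantile-normalised them, with a median of 5.80 in each column, and each column ranks the spots as the array's own processed signal does. Its scale is therefore log2 with no centring per gene, and it was used only as an alternative.

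Each array held 43803 non-control and 1417 control spots. Control spots and 2 to 10 outlier spots per array were left out, no spot was saturated, and the 50 probes with 5 spots each were averaged, which gave 43603 probes of 60 bases. The 75th percentile of the signal lay between 538 and 1073, the median between 38.0 and 101, and 60.9% to 69.7% of probes were well above background. Values analysed were log2 of the processed signal minus the array's own 75th percentile. A probe was tested when it was well above background on both arrays of at least 1 group, which kept 29284 probes (67.2%), 12 of them with a missing spot. A group in which no array measured a probe gives only a bound, computed from the higher of the dimmest signal well above background and the probe's own. Correlations between the replicates of a group lay between 0.957 and 0.973, and no pair held identical values.

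Probes were named by the gene names in the array files and by matching accessions to the RefSeq gene table of assembly SLM_r2.1, used for names alone. 2277 probes matched 985 reference genes, and 5073 probes had a name or description of any kind, while 13044 are described in the files as unknown. Labels that name a clone or a library were not counted as descriptions, which was settled after a first set of values had been seen. Where several probes matched a gene, the one with the highest mean signal gave its value. Pattern matching left some genes out and let some in: CHS1 is counted among key ripening genes and not in the flavonoid list, 20ox-2 is not in the gibberellin list, the seed list holds signal recognition particle genes, and the sterol list holds an acyltransferase-like gene and GABA-TP2.

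A linear model with a mean for each of the 4 groups was fitted to all 8 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 4 residual and 2.44 prior degrees of freedom). The contrasts were the knockdown effect averaged over lines, that effect within each line, its difference between lines, and the line difference among wild-type and among knockdown siblings. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg within a contrast, and a call is an adjusted p below 0.05, with the number changed at least 2-fold beside it. The 23 gene lists comprised the knocked-down genes and key ripening genes, ethylene biosynthesis, perception and response factors, carotenoid, cell wall, cuticle, aroma, flavonoid, photosynthesis, MADS-box, sugar, auxin, gibberellin, abscisic acid, heat shock, defence, sterol, cell division and ribosomal genes, and markers of seed and vascular tissue. They were tested with limma's camera at a preset correlation of 0.01 where at least 5 genes were tested, adjusted over lists within a contrast, with an estimated correlation beside it. No camera call at the preset correlation held with the estimated one. Groups, tests, lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule names the knocked-down and key ripening genes whatever their values, up to 4 called members of each other list, the 10 largest described rises and falls of the pooled contrast with the same sign in both lines, the 5 largest in each direction of the other contrasts, and the 3 smallest p-values where a contrast had no call.

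Per the file headers each slide held 1 array of every group, and the slide equals the replicate number and the scan, so these cannot be separated. Each group had the same position on both slides, so position and group cannot be told apart. Same-numbered samples deviated together from their group means: the 6 correlations between pairs of groups were 0.501, 0.629, 0.382, 0.333, 0.492 and 0.467. The numbers were therefore taken to pair the samples. The value with the number as a block is given where it changes the call of a named value or of a set test. It is also given where it moves a contrast's count of probes by over 1.5 times. Members called within a list, and the shares of all genes called, were counted only without the block. How the block moves these counts was not examined. Within 1 slide the pooled contrast alone could be tested.

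Alternatives were normexp background correction with an offset of 50, quantile normalisation, scaling to the median, the deposited value table, no filter or a strict filter on dim probes, a variance trend with robust estimation, the block, each slide alone, each array left out, models with fewer terms, fits on the arrays of 1 line, other set tests and all probes of a gene. The procedure was tested on simulated data for 29272 probes with 200 changed. For the pooled contrast it recovered 2, 36, 46 and 50 of 50 probes changed by 1, 2, 4 and 6 on the log2 scale, with 5 false calls. In line 1-10 it recovered 0, 17, 42 and 46 of 50 with 7 false calls, and in line 1-30 1, 19, 41 and 46 of 50 with 10 false calls. With no change simulated it made 0 calls for the pooled contrast. The simulated noise was independent between probes and between arrays and held no slide effect, unlike these arrays. The false calls therefore do not give the error rate in the real data. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. No genome build or coordinates were needed for these values.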

Results

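Transcript levels were measured in tomato fruit at the breaker stage, when the first colour appears, in the dwarf cultivar Micro-Tom. The question was which transcripts differ when the MADS-box transcription factors FUL1 (also called TDR4) and FUL2 (also called MBP7), tomato relatives of Arabidopsis FRUITFULL, are knocked down. Transgenic progeny of 2 primary transformed lines, 1-10 and 1-30, were set against wild-type progeny of the same line, which had lost the transgene by segregation. The 4 groups held 2 samples each, and each sample was hybridised to its own 1-colour array of 43603 probes. Between 60.9% and 69.7% of the probes of an array were well above background. Correlations between arrays across probes lay between 0.922 and 0.973. The number of arrays limits the precision of every value below. No label states that the 2 samples of a group came from separate plants, so p-values measure only the spread between these samples, which may be technical. In a principal component analysis the genotypes separated on component 1, with 30.3% of the variance, where knockdown arrays lay between 28.6 and 84 and wild-type arrays between -114.7 and -10.4. Lines separated on component 2 (26.3%), and the 2 slides, which are also the replicate numbers, on component 3 (21.5%).

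FUL1 and FUL2 were lower in every knockdown array than in every wild-type array. FUL1 stood at a normalised log2 level of 7.27 and 7.26 in the wild-type arrays of line 1-10, and at 8.03 and 7.53 in those of line 1-30. The knockdown arrays gave 3.06 and 3.03 in line 1-10, and 4.17 and 1.72 in line 1-30. FUL2 gave 5.07 and 4.71 in wild-type arrays of line 1-10, and 6.53 and 4.85 in those of line 1-30. Its knockdown values were 2.87 and 2.47 in line 1-10, and 3.31 and 2.37 in line 1-30. Over both lines FUL1 fell 23.1-fold (log2 fold change -4.53, SE 0.51, n = 4 arrays per genotype, adjusted p = 0.00729) and FUL2 fell 5.78-fold (-2.53, SE 0.42, adjusted p = 0.0211). FUL1 had 1 probe. The other FUL2 probes gave -2.73 (adjusted p = 0.00401) and -2.66 (adjusted p = 0.0731). All these spots were well above background, and a probe that also detects transcripts of the transgene would understate the loss. Within a line, FUL1 passed the threshold in line 1-30 (-4.84, adjusted p = 0.0251) and not in line 1-10 (-4.22, adjusted p = 0.067), and FUL2 passed in neither (-2.22, adjusted p = 0.171, and -2.85, adjusted p = 0.0577). FUL2 lost its pooled call without either array of wild-type line 1-10 (adjusted p = 0.0635 and 0.058) or of knockdown line 1-10 (0.0743 and 0.0873), or without replicate 2 of knockdown line 1-30 (0.0685). FUL1 lost its call in line 1-30 without either wild-type array of that line (0.144 and 0.094) or either knockdown array of line 1-10 (0.0574). The related genes MBP10 and MBP20 were not matched to a probe.

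**Figure D1:**
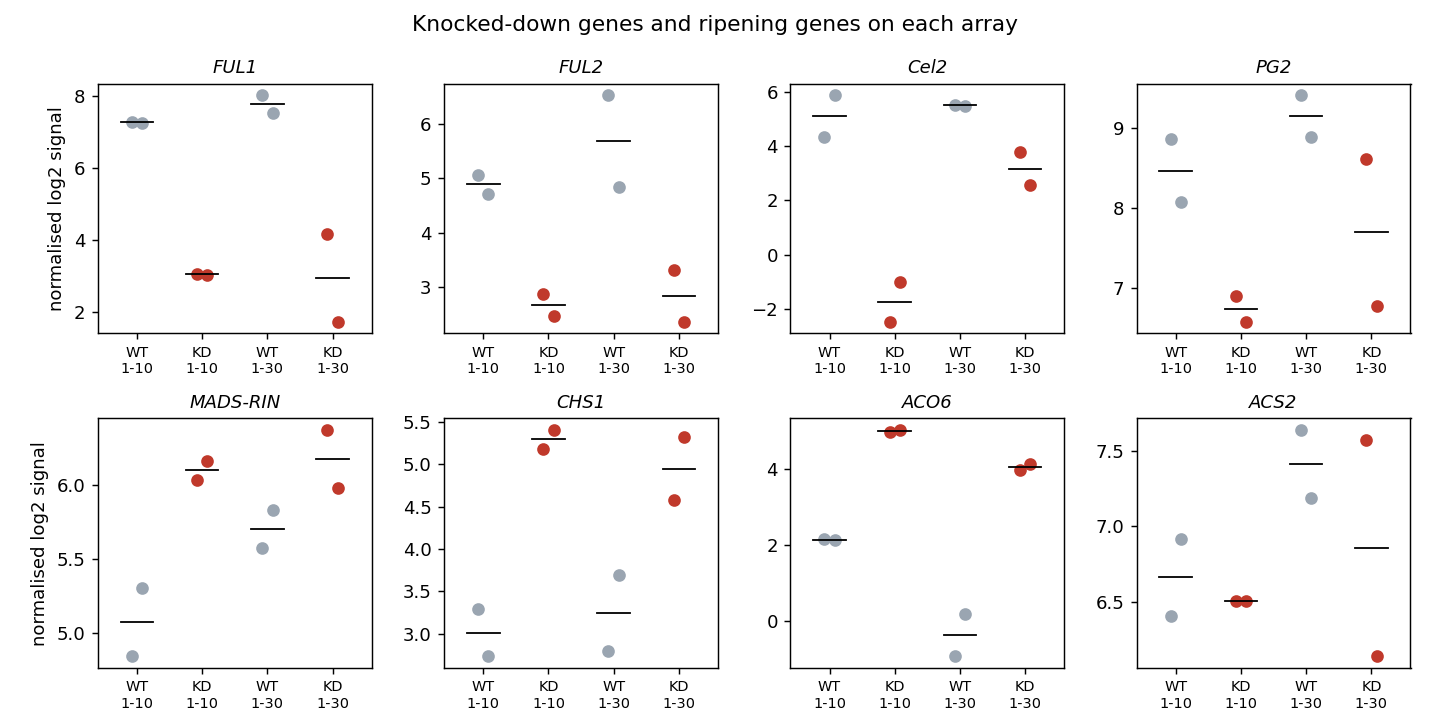
Normalised log2 signal of 8 genes on each array (y axis), with wild-type arrays in grey, knockdown arrays in red and a line at each group's mean of 2 arrays. FUL1 lies between 7.26 and 8.03 in wild-type arrays and between 1.72 and 4.17 in knockdown arrays, while ACS2 gives a pooled log2 fold change of -0.36 that did not pass the test.

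Among known ripening genes, the knockdown fruit had much less transcript of the endoglucanase Cel2, a cell wall enzyme of ripening fruit, and more of CHS1, chalcone synthase, the entry enzyme of flavonoid synthesis. Cel2 fell 24.1-fold (log2 fold change -4.59, SE 0.51, n = 4 arrays per genotype, adjusted p = 0.00696), and CHS1 rose 3.99-fold (2.00, SE 0.30, adjusted p = 0.0155). Cel2 had -6.84 in line 1-10 and -2.34 in line 1-30 (adjusted p = 0.145), and the test of that difference gave adjusted p = 0.409. ZDS, a carotene desaturase on the way to lycopene, fell (-1.22, SE 0.17, adjusted p = 0.0116), as did loxC, a lipoxygenase of C6 volatile synthesis (-1.03, SE 0.21, adjusted p = 0.0396). Without the replicate number as a block, these were the calls among 22 key ripening genes, 1 up and 3 down, with 18 not called. Adjusted over the list alone, 5 rose and 4 fell. The polygalacturonase PG2, which degrades pectin, missed the threshold at its brightest probe (-1.59, SE 0.44, adjusted p = 0.0871, and 0.0213 with the replicate number as a block), while its other 5 probes were all called, between -1.89 and -2.76. The second ZDS probe gave -0.97 (adjusted p = 0.052), and 1 of 3 loxC probes also missed the threshold (-1.10, adjusted p = 0.0716). The list as a whole had a median of 0.12 and a mean of -0.14, and the set test, with the sign of the mean, gave adjusted p = 0.918.

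The regulators and ethylene genes of that list were not called at their brightest probe, though some were with the replicate number as a block. The ripening factors MADS-RIN and NOR had log2 fold changes of 0.75 (SE 0.20, adjusted p = 0.0797, and 0.0454 with the block) and 1.27 (SE 0.39, adjusted p = 0.116), TAGL1 of 0.95 (SE 0.28, adjusted p = 0.106, and 0.0164 with the block), AP2a of 0.93 (SE 0.27, adjusted p = 0.0961, and 0.0332 with the block) and HB-1 of 0.28 (adjusted p = 0.473). The second TAGL1 probe was called at 1.07 (adjusted p = 0.0224). Genes of ethylene synthesis gave -0.36 for ACS2 (SE 0.35, adjusted p = 0.655), 0.26 for ACS4 (SE 0.59, adjusted p = 0.871) and 0.36 for ACO1 (SE 0.21, adjusted p = 0.407). The receptors Never-ripe and ETR4 gave 0.05 and -0.34, and the ethylene-responsive genes E8 and E4 (LOC544026) 0.18 and -0.05, with adjusted p between 0.784 and 0.929. The remaining members were Psy1, phytoene synthase (-0.58, adjusted p = 0.145, and 0.0379 with the block), PDS (0.18, adjusted p = 0.626), the expansin EXP1 (-1.11, adjusted p = 0.208), the galactosidase TBG4 (0.95, adjusted p = 0.159, and 0.0195 with the block; 1 of its 4 probes was called, at 1.07) and ADH2 (-0.29, adjusted p = 0.539). CNR, CRTISO, PL and GLK2 were not matched to a probe.

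Cell wall genes moved both ways in the pooled comparison. Of 45 tested members 6 rose and 5 fell (10 and 6 adjusted over the list alone). The beta-expansin EXPB2 rose at least 21.4-fold (log2 fold change 6.44, SE 0.27, adjusted p = 0.000998) and was not well above background on any wild-type array. A transcript like the non-catalytic subunit of a polygalacturonase, TA37131_4081, rose at least 5.92-fold (4.32, SE 0.48, adjusted p = 0.00713), also from below background. Another beta-expansin, LOC100134906, fell at least 11.3-fold (adjusted p = 0.0106), and only 1 of 4 knockdown arrays, in line 1-30, measured it. A bound of this kind sets the bright group against the dimmest signal that counted as well above background, since a dim spot gives only an upper limit. Pooled bounds are means over the lines on the log2 scale, with each dim spot of the lower genotype at its limit. The list's median was 0.64 and its set test gave adjusted p = 0.108.

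Genes of volatile and carotenoid synthesis were mostly lower where they were called. Of 17 aroma genes 3 fell and 1 rose (4 and 2 adjusted over the list alone). The falls were loxC, the hydroperoxide lyase HPL (log2 fold change -1.55, SE 0.25, adjusted p = 0.0198), which acts after lipoxygenase, and AAT, an alcohol acyltransferase (-2.46, SE 0.46, adjusted p = 0.0292). The rise was a short-chain alcohol dehydrogenase, TC212746, at least 46.6-fold (adjusted p = 0.00104), which only the wild-type arrays of line 1-30 measured among wild types. Of 14 carotenoid and isoprenoid genes 2 fell and 0 rose (4 and 0 adjusted over the list alone). CrtR-b2, a carotene hydroxylase, fell by 1.51 on the log2 scale (SE 0.19, adjusted p = 0.00909), beside ZDS. The set tests of these lists gave adjusted p = 0.108 (median -0.40) and 0.0956 (median -0.19).

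Of 13 genes of ethylene biosynthesis, ACO6, an ACC oxidase, was the only call and rose 12.4-fold (log2 fold change 3.63, SE 0.27, adjusted p = 0.00238). Of 17 genes of ethylene perception and signalling, EIL2, a transcription factor of the pathway, rose (2.71, SE 0.44, adjusted p = 0.0196) and none fell, and 0 of 11 ethylene response factors were called. Adjusted over the list alone these counts were the same. In the auxin list 3 of 23 rose and 0 fell (4 and 0 adjusted over the list alone): IAA9 (0.75, SE 0.17, adjusted p = 0.048), IAA27 (1.18, SE 0.18, adjusted p = 0.0168) and TA48625_4081, like an auxin response factor (1.51, SE 0.21, adjusted p = 0.0122). Among 17 MADS-box factors MADS1 rose (1.03, SE 0.21, adjusted p = 0.038), and TA56518_4081 (-1.50, SE 0.28, adjusted p = 0.0276; 2 of 4 knockdown arrays measured it) fell with FUL1 and FUL2; adjusted over the list alone, 5 rose and 3 fell. No member was called in the gibberellin (6 tested) or abscisic acid (5 tested) lists, by either adjustment, but the gibberellin oxidase gene 20ox-2, named below, fell and was not matched to its list by name. Set tests gave adjusted p = 0.277 for ethylene biosynthesis, 0.918 for perception, 0.905 for response factors, 0.265 for both auxin and MADS-box factors, 0.468 for gibberellin and 0.991 for abscisic acid, whose test pointed down although its median and mean were 0.06 and 0.03.

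Sugar metabolism and transport gave rises without falls: of 53 members of the sugar, starch and organic acid list 5 rose and 0 fell, and 5 and 0 adjusted over the list alone. The cell wall invertase lin5 rose 13.6-fold (log2 fold change 3.76, SE 0.35, adjusted p = 0.00403), and the sucrose transporters SUT4 (2.16, SE 0.17, adjusted p = 0.00291) and TC192483 (2.66, SE 0.39, adjusted p = 0.0147) rose too. Of wild-type arrays, 3 measured lin5 and 2 measured TC192483. Another invertase, LIN9, was called higher (adjusted p = 0.0245) but measured only on the 2 knockdown arrays of line 1-10, so no pooled fold is given, and it changed sign to -0.13 with normexp background correction. The hexokinase hxk1 (1.61, SE 0.20, adjusted p = 0.00868) was named after its value was seen. The flavonoid and phenylpropanoid list, to which CHS1 did not match by name, had 2 rises and 0 falls among 13 (4 and 1 adjusted over the list alone), TA37481_4081, like a 4-coumarate ligase (1.53, SE 0.23, adjusted p = 0.0154), and TA54543_4081, like an O-methyltransferase (1.09, SE 0.18, adjusted p = 0.0198). Set tests gave adjusted p = 0.664 for the sugar list and 0.225 for the flavonoid list.

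In photosynthesis and chlorophyll 1 of 33 rose and 1 fell (1 and 1 adjusted over the list alone): the chlorophyll-binding protein TA36129_4081 (log2 fold change 2.30, SE 0.42, adjusted p = 0.0268) and PSBO of photosystem II (-1.56, SE 0.19, adjusted p = 0.00862). Its median was -0.09 and its mean 0.12, with a test pointing down (adjusted p = 0.918). Heat shock and chaperone genes gave 2 rises and 1 fall among 38 (2 and 2 adjusted over the list alone), AW932718 (2.76, SE 0.22, adjusted p = 0.00291) and TA51875_4081 (2.56, SE 0.52, adjusted p = 0.0365) against HSP21 (-1.30, SE 0.21, adjusted p = 0.0195); the set test gave adjusted p = 0.905. Of 16 defence genes, snakin-like AI779761 rose (3.71, SE 0.83, adjusted p = 0.0499; measured on 2 of 4 wild-type arrays) and the proteinase inhibitor LOC543955 fell (-2.82, SE 0.38, adjusted p = 0.0106), with 3 and 1 adjusted over the list alone and a set test at adjusted p = 0.571. Of 4 cuticle genes the acyltransferase GPAT fell (-1.15, SE 0.18, adjusted p = 0.0184) and GPAT4-like TA42757_4081 rose at least 3.25-fold (adjusted p = 0.0308; 1 of 4 wild-type arrays measured it, in line 1-10); adjusted over the list alone 2 rose and 2 fell, and the list was too small for a set test. No member was called among 28 cell division genes (adjusted p = 0.991) and 14 sterol and glycoalkaloid genes (adjusted p = 0.582), and adjusted over the list alone none was either.

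Of the lists for other tissues in the fruit, lignification and vascular tissue had 2 rises and 0 falls among 13 by both adjustments: the extensin X55694 (log2 fold change 2.55, SE 0.31, adjusted p = 0.00868; 3 of 4 wild-type arrays measured it) and a cellulose synthase-like transcript, TA55960_4081 (1.88, SE 0.31, adjusted p = 0.0202). Its set test gave adjusted p = 0.119, and the seed storage and maturation list, with 0 of 14 called by both adjustments, gave 0.905. The ribosomal proteins (reference group) were the only one of 21 lists tested to pass: 60 of 70 members had negative values, the mean was -0.24, and 3 fell, all annotated as plastid proteins, namely S5 (TA37505_4081, -1.12, adjusted p = 0.0208), S3 (TA45829_4081, -0.86, adjusted p = 0.029) and L20 (TC211209, -0.96, adjusted p = 0.0207). The same 3 to 0 split held adjusted over the list alone. The set test gave adjusted p = 0.00333, but adjusted p = 0.745 with an estimated correlation. The value was 0.000879 with the replicate number as a block, 0.205 on slide 1 alone, 5.85e-05 on slide 2 alone, 0.101 with normexp, 0.0946 with dim probes kept and 0.146 without replicate 2 of wild-type line 1-10. With the block, 3 lists passed: these proteins, aroma volatile synthesis (0.0407, lower) and cell wall modification (0.0407, higher).

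**Figure D2:**
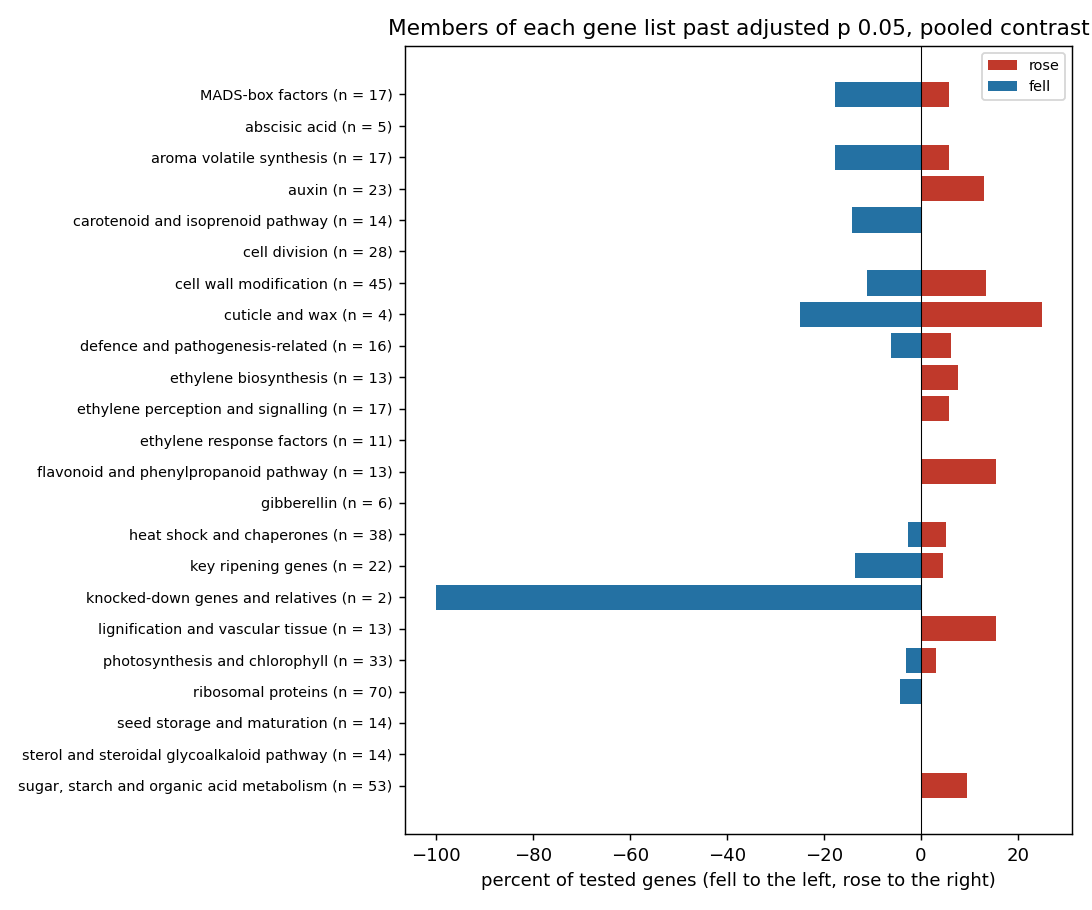
Percent of the tested genes of each fixed list that fell (left) or rose (right) in the pooled comparison, with the number of tested genes beside each name. Cell wall modification shows calls on both sides, 6 up and 5 down of 45, and the sugar list has 5 rises of 53 and 0 falls.

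Across the whole array, the largest fitted rises with a description were in the subtilisin-like protease SBT2 (at least 63.8-fold, adjusted p = 0.00553; 1 of 4 wild-type arrays measured it, in line 1-30), EXPB2, TC212746, the tonoplast aquaporin TIP (log2 fold change 5.07, SE 0.49, adjusted p = 0.00471) and nodulin-like DB711969 (5.01, SE 0.17, adjusted p = 0.000724). They were followed by the glycine-rich protein X55693 (4.78), the cytochrome P450 TA43614_4081 (4.52), the ferric-chelate reductase FRO1 (4.47), the zinc finger factor TA56993_4081 (4.34) and TA37131_4081. FRO1 and TA56993_4081 were each measured on 3 of 4 wild-type arrays. The largest fitted falls with a description were in a trypsin inhibitor-like transcript, LOC544001 (at least 11.2-fold, adjusted p = 0.00715; 1 of 4 knockdown arrays measured it, in line 1-30), in Cel2 and FUL1, in the salicylic acid methyltransferase-like TA52356_4081 (at least 10.4-fold, adjusted p = 0.00426) and in LOC100134906. Next came another probe of LOC543955 (-3.59; 3 of 4 knockdown arrays measured it), the carbonic anhydrase ca3 (-3.21, SE 0.28, adjusted p = 0.00371), the nitrate transporter NRT2;1 (at least 3.68-fold, adjusted p = 0.0261), the gibberellin oxidase gene 20ox-2 (at least 2.12-fold, adjusted p = 0.0102) and the PG2 probe at -2.76. Of wild-type arrays, 3 measured NRT2;1 and 3 measured 20ox-2.

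In all, 2147 of 29284 tested probes were called in limma's moderated test of the pooled knockdown effect, 1281 higher and 866 lower in the knockdown, and 1822 of these changed at least 2-fold. They stood for 1745 accessions, of which 331 probes had a description. At 1 probe per gene, 4.54% of 21701 genes rose and 3.02% fell. The count was 817 with normexp background correction (807 of them shared), 1368 with dim probes kept, 4844 with the replicate number as a block, 0 on slide 1 alone and 157 on slide 2 alone. Leaving out any 1 of the 8 arrays also moved it by over 1.5 times, down to 571 at the lowest.

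Within line 1-10, among probes with a description, EXPB2 rose at least 26.7-fold (log2 fold change 6.60, SE 0.39, n = 2 arrays per group, adjusted p = 0.00951), SBT2 at least 43.7-fold (adjusted p = 0.0486), TC212746 at least 46.8-fold (adjusted p = 0.00951), TIP by 5.09 (SE 0.69, adjusted p = 0.0391) and TA43614_4081 by 4.74 (SE 0.67, adjusted p = 0.0421). Cel2 fell (-6.90 at the named probe, SE 0.74, adjusted p = 0.0279), LOC544001 fell at least 28.3-fold (adjusted p = 0.0312) and an actin-like transcript, BI927156, at least 3.10-fold (adjusted p = 0.0376). A histone H4 transcript, TA55540_4081 (-3.32, SE 0.45, adjusted p = 0.0391), and TA55630_4081 (-2.82, SE 0.36, adjusted p = 0.0352; 1 of 2 knockdown arrays measured it) fell in line 1-10. In line 1-30 TA55540_4081 had 1.17, TA55630_4081 was not well above background on wild-type arrays, and tests of the difference gave adjusted p = 0.222 and 0.177. The count was 235 probes, 152 higher and 83 lower, all at least 2-fold. The lists that passed the set test were all lower: ribosomal proteins (mean -0.35, 66 of 70 negative, adjusted p = 2.37e-05), carotenoid and isoprenoid genes (mean -0.43, adjusted p = 0.0288) and heat shock genes (mean -0.26, 30 of 38 negative, adjusted p = 0.0288). With an estimated correlation their adjusted p were 0.695, 0.512 and 0.695. Quantile normalisation ended the calls of the carotenoid and isoprenoid pathway and of heat shock and chaperones (0.109 for both), as did the loss of replicate 1 of wild-type line 1-10 (0.132 and 0.524) or of replicate 2 of knockdown line 1-10 (0.0647 for both), and without replicate 2 of wild-type line 1-10 the carotenoid list and the ribosomal proteins (reference group) gave 0.065 and 0.161. The count of probes was 87 with normexp, 98 with dim probes kept, 975 with the replicate number as a block and 0 with the 4 arrays of the line alone; without an array it was 0 or 1 for the line's own arrays, 39 for each wild-type and 54 for each knockdown array of line 1-30.

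Within line 1-30, SBT2 (log2 fold change 6.97 at another probe, SE 0.93, n = 2 arrays per group, adjusted p = 0.0189; 1 of 2 wild-type arrays measured it), X55693 (6.35, SE 0.50, adjusted p = 0.006), DB711969 (6.32, SE 0.25, adjusted p = 0.00228) and EXPB2 (at least 17.1-fold, adjusted p = 0.0041) rose. A beta-glucanase annotated Q`b also rose (5.95, SE 0.95, adjusted p = 0.0282; 1 of 2 wild-type arrays measured it); its value in line 1-10 was -0.70 and the test of the difference gave adjusted p = 0.358. FUL1, LOC100134906 (-4.54, SE 0.72, adjusted p = 0.0278; 1 of 2 knockdown arrays measured it), TA52356_4081 (at least 11.8-fold, adjusted p = 0.0114), LOC543955 (-3.97, SE 0.73, adjusted p = 0.04) and ca3 (-3.81, SE 0.40, adjusted p = 0.00966) fell. The count was 1182 probes, 857 higher and 325 lower, all at least 2-fold. Heat shock genes (mean 0.66, 27 of 38 positive) and flavonoid genes (mean 1.08) passed the set test upwards, each at adjusted p = 0.0495; with an estimated correlation the adjusted p were 0.654 and 0.497. With the replicate number as a block, the flavonoid and phenylpropanoid pathway gave adjusted p = 0.116, with normexp 0.276, with quantile normalisation 0.0619, without replicate 1 of wild-type line 1-30 0.142 and without replicate 2 of knockdown line 1-30 0.174. The list of heat shock and chaperones gave 0.134 without replicate 1 of wild-type line 1-30 and 0.0724 without replicate 1 of knockdown line 1-30. The count of probes was 213 with normexp, 650 with dim probes kept, 3062 with the block, 66 with the 4 arrays of the line alone, 60 to 294 without an array of the line and 461 without either knockdown array of line 1-10.

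The knockdown effects of the lines ran in the same direction for most called genes. Both lines called 124 probes higher and 46 lower, where independent lists would share 4.45 and 0.921, and 1 probe was called in opposite directions. Of the 235 calls in line 1-10, 224 had the same sign in line 1-30, and of the 1182 calls in line 1-30, 1069 had the same sign in line 1-10. Across all tested probes, which are not independent replicates, the log2 fold changes correlated with Pearson's r = 0.541 and Spearman's rho = 0.468. No array served in both comparisons, but both tests took their spread from all 8 arrays. The lists of calls are thus not independent, and 4.45 and 0.921 may be too low.

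**Figure D3:**
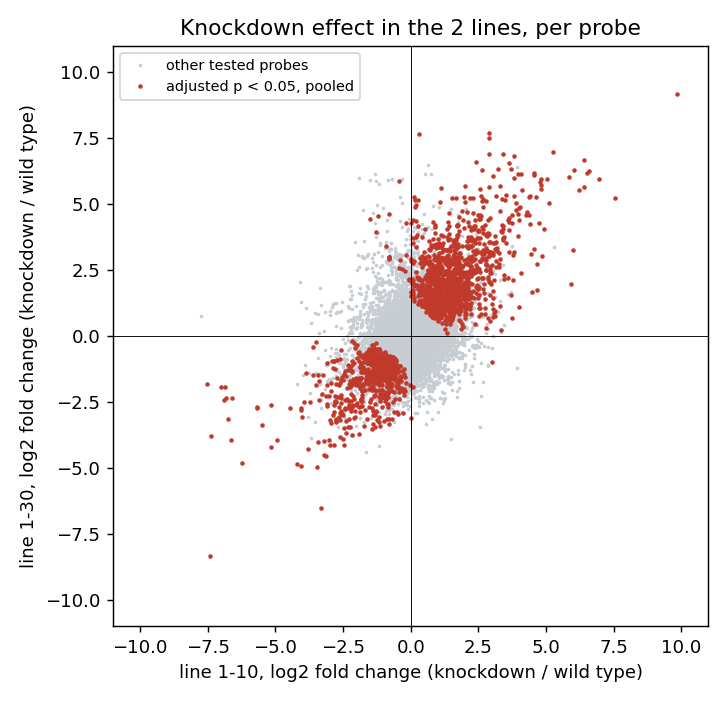
Log2 fold change, knockdown over wild type, of each tested probe in line 1-10 (x axis) and line 1-30 (y axis), with probes called in the pooled comparison in red. Across all probes Pearson's r was 0.541, and 65.3% of probes had the same sign in both lines.

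As a group, heat shock genes differed between the lines in how they responded by the set test at the preset correlation, and not with an estimated one. Their mean effect was 0.92 lower on the log2 scale in line 1-10 than in line 1-30 (mean of the difference -0.92, 32 of 38 members negative), with adjusted p = 1.53e-07 in the set test, but adjusted p = 0.446 with an estimated correlation. Cell division (-0.52, 22 of 28 negative), flavonoid (-1.26) and photosynthesis genes (-0.61, 22 of 33 negative) were also lower in line 1-10 by the test, each at adjusted p = 0.0238. With an estimated correlation the adjusted p were 0.446, 0.446 and 0.666. The means of cell division and of flavonoid and phenylpropanoid pathway genes turned to 0.03 and 0.00 with normexp (adjusted p = 0.509 for both), where the median of all probes was 0.23 against 0.03 as reported, while photosynthesis and chlorophyll kept its sign (-0.10, adjusted p = 0.0975). With the replicate number as a block the flavonoid list gave adjusted p = 0.074 and photosynthesis 0.0524, while defence and pathogenesis-related genes and ribosomal proteins (reference group) were called, both at 0.0262.

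No single probe passed the test of a difference between the lines. limma called 0 probes, with 1899 at an unadjusted p below 0.05 and a smallest adjusted p of 0.155, and the block fit also called 0. The smallest p-values, which failed the threshold, belonged to ES896037, AK247170 and AW625371, all at adjusted p = 0.155. All 3 were well above background on both knockdown arrays of line 1-30, and ES896037 on 1 array of another group, so no size is given.

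The wild-type siblings of the lines also differed, at some probes by over 32-fold. Higher in line 1-10 were b3gat3 (at least 93.1-fold, n = 2 arrays per group, adjusted p = 0.00139), the plastidic hexokinase HXK4 (at least 62.9-fold, adjusted p = 0.000578), remorin rem-1 (log2 difference 5.84, SE 0.82, adjusted p = 0.0344), ER68 (5.68, SE 0.90, adjusted p = 0.0491) and the xyloglucan transferase XET2 (5.25, SE 0.53, adjusted p = 0.0117). Of the arrays of line 1-30, 1 of 2 measured rem-1 and 1 of 2 measured ER68. Lower in line 1-10 were OPR3, an oxophytodienoate reductase of jasmonate synthesis (at least 148-fold, adjusted p = 0.00122), the metallothionein MT2 (at least 21.6-fold, adjusted p = 0.00267), BP889887 (at least 23.4-fold, adjusted p = 0.00269), TC204965 (at least 19.6-fold, adjusted p = 0.0135) and a serine hydroxymethyltransferase-like transcript, TA39682_4081 (-5.96, SE 0.55, adjusted p = 0.00847). Probes of one gene did not always give the same difference. MT2 had the same direction at its other probe, while the other probes of b3gat3 gave -0.30 to 0.55, that of rem-1 gave 1.19 and that of ER68 gave 0.01. In total 343 probes were called, 205 higher and 138 lower in line 1-10, all at least 2-fold. The count was 115 with normexp, 119 among probes well above background on all arrays and 725 with the replicate number as a block, and without an array of either wild-type group it lay between 80 and 89. The majority of higher calls (59.8%) was not stable. It was 35.7% with normexp, where the median of all probes was -0.24 against -0.04 as reported, between 45.1% and 50% without an array of either wild-type group, and 49.4% without either knockdown array of line 1-10.

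Among the knockdown siblings 217 probes differed between the lines, 90 higher and 127 lower in line 1-10. The 10 genes named among wild-type siblings were called in the same direction here. The same probes were compared, so a sequence variant under a single probe would repeat in this comparison. Of these genes only b3gat3, rem-1, ER68 and MT2 had another tested probe. Higher in line 1-10 were b3gat3 (at least 87.7-fold), HXK4 (at least 36.7-fold), rem-1 (5.83), ER68 (6.18; 1 of 2 arrays of line 1-30 measured it) and XET2 (8.15). Lower were OPR3 (at least 259-fold), MT2 (at least 266-fold), BP889887 (at least 62.5-fold), TC204965 (at least 17.2-fold) and TA39682_4081 (-6.32), with adjusted p between 0.000734 and 0.0483 over the 10. Wild-type and knockdown siblings shared 147 calls in the same direction, where independent lists would share 1.23, and 1 call was opposite. Both tests took their spread from all 8 arrays, so these lists are not independent and 1.23 may be too low. The 88 wild-type calls with a fitted log2 difference beyond 5, which is no bound where a group was dim, all had the same sign in the knockdown siblings. The knockdown count was 110 with normexp, 22 among probes well above background on all arrays (13 higher and 9 lower, so the split turned), and between 88 and 107 without an array of either knockdown group.

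**Figure D4:**
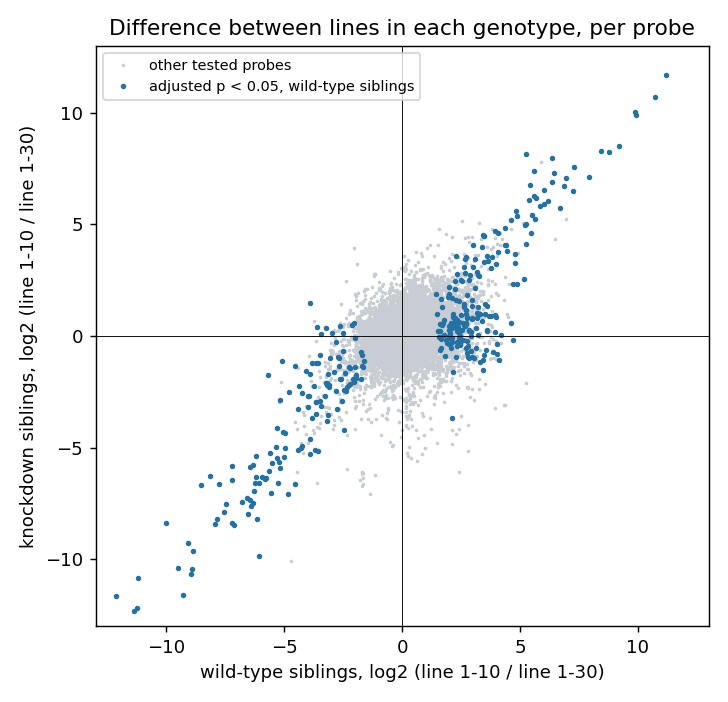
Log2 difference between line 1-10 and line 1-30 of each tested probe among wild-type siblings (x axis) and among knockdown siblings (y axis), with probes called among wild-type siblings in blue. Over those 343 probes chosen for their difference on the x axis, which raises the value, the differences correlated at r = 0.914.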

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

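The tests of a single array and of members that vary together, for heat shock genes, were chosen after the result was seen; the slide test was not. With 2 samples per group no test for an outlying sample was run.

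Heat shock and chaperone genes were singled out because their knockdown effect differed between the lines by the set test of that difference (adjusted p = 1.53e-07, mean difference -0.92). Their mean normalised log2 level was 2.71 and 2.19 on the wild-type arrays of line 1-10 and 1.75 and 1.93 on those of line 1-30, against 2.23 and 2.15, and 2.64 and 2.35, on the knockdown arrays. A single array as the whole source was argued against, since the mean difference lay between -1.178 and -0.658 over the fits without 1 array. The largest adjusted p of the set test over these fits was 0.000741. That p decides nothing here, since it used the preset correlation of 0.01, while the correlation estimated from all arrays was 0.181. An effect of 1 slide as the whole source was argued against too. The mean difference was -1.37 on slide 1 and -0.47 on slide 2, with 30 of 38 members negative on slide 2. Each slide gave 1 array per group, and an effect equal on all arrays of a slide cancels from this difference. What stays open is that these genes vary together from sample to sample, since the adjusted p was 0.446 with an estimated correlation, and a difference in temperature or handling between samples, or a biological difference between the lines, may underlie the pattern and was not tested.

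Cell division, flavonoid and phenylpropanoid, and photosynthesis and chlorophyll genes were singled out by the same test of a difference between the lines. Cell division gave adjusted p = 0.0238 with a mean difference of -0.52, and lost the call without replicate 2 of wild-type line 1-10 (0.164), replicate 1 of wild-type line 1-30 (0.252) or replicate 2 of knockdown line 1-30 (0.105). The flavonoid and phenylpropanoid pathway gave adjusted p = 0.0238 with a mean difference of -1.26, and had -0.07 among probes well above background on all arrays (adjusted p = 0.444). It lost the call without replicate 1 of wild-type line 1-10 (0.0903), of wild-type line 1-30 (0.217) or of knockdown line 1-10 (0.061), or replicate 2 of knockdown line 1-30 (0.223). Photosynthesis and chlorophyll gave adjusted p = 0.0238 with a mean difference of -0.61, and lost the call without replicate 1 of wild-type line 1-30 (0.192), of knockdown line 1-10 (0.22) or of knockdown line 1-30 (0.0748), or replicate 2 of wild-type line 1-10 (0.624).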

How the results depend on the processing

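No alternative was added after the data were seen. FUL1 kept its direction and pooled call in the settings run except slide 1 alone (-4.03, adjusted p = 0.179), and the interaction gave 0 calls wherever it was fitted. With normexp the pooled count was 817, line 1-10 gave 87, line 1-30 213, wild-type siblings 115 and knockdown siblings 110, and LIN9 changed sign to -0.13; with dim probes kept the first 3 counts were 1368, 98 and 650, where more probes share the adjustment, and the strict filter, which drops probes dim on any array, gave 119 for wild-type and 22 for knockdown siblings. With the replicate number as a block they were 4844, 975 and 3062, and 725 for wild-type siblings; slide 1 alone gave 0 and slide 2 alone 157, and the arrays of one line alone gave 0 for line 1-10 and 66 for line 1-30, all with fewer samples. The cause was not tested for normexp. Of the set tests, where 1 list passed, an estimated correlation gave 0, fry 6, all probes 3, median scaling 4, no filter 7, the block 3, slide 1 alone 0, slide 2 alone 3. The 6 lists called by fry were others: carotenoid (adjusted p = 0.0106), auxin (0.0125), cell wall (0.017), and ethylene biosynthesis, lignification and sugar (0.033 each). By fry the ribosomal proteins, the list that passed as reported, were not called (adjusted p = 0.199).

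Without 1 array each, the pooled count lay between 571 and 1416, line 1-10 between 0 and 54, line 1-30 between 60 and 889, wild-type siblings between 80 and 219, knockdown siblings between 88 and 168, lists between 0 and 3, and the correlation between lines between 0.43 and 0.552; the lone sample left is assumed to vary like the other groups. Pooled counts without replicates 1 and 2 were 1416 and 1181 for wild-type line 1-10, 701 and 999 for wild-type line 1-30, 571 and 571 for knockdown line 1-10, and 1109 and 1047 for knockdown line 1-30. Quantile normalisation, the deposited table, median scaling and the robust variance kept the pooled count between 1555 and 2345. Of 1800 comparisons of named values, 1308 kept direction and side of the threshold, 468 lost the call (298 without an array, from 25 to 45 of the 85 called values for any 1 array, and 97 within a slide), 8 gained it, 1 reversed and 15 uncalled values changed sign. Spots near background give only bounds for dim genes.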

Other observations

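The gene groups and single probes in this part were chosen after the values were seen, as were the tests of scaling, of the line difference within each slide, of the slide as a block, of the pooled effect across slides and of plastid ribosomal proteins; the others were written before.

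Aquaporins, water channels of the plasma membrane and tonoplast, gave positive values for all 6 tested genes in the pooled comparison (mean log2 fold change 1.68), and 3 rose: TIP, TA38086_4081 (0.99, adjusted p = 0.0261) and TC214790 (1.01, adjusted p = 0.0474). Of these 6, TC214790 had 2.99 in line 1-10 and -0.97 in line 1-30, and DV105470, which was not called, 2.84 and -1.12. The set test gave adjusted p = 0.000119, and adjusted p = 0.0908 with an estimated correlation. Of 14 extensins and glycine-rich proteins 3 rose, X55693, X55694 and TA42078_4081 (2.51, SE 0.16, adjusted p = 0.00208); the mean was -0.09 in line 1-10 and 1.81 in line 1-30 (pooled adjusted p = 0.0249, and 0.239 with an estimated correlation). Of 6 proteinase inhibitors, defence proteins against insect digestion, LOC543955 and LOC544001 (at least 9.97-fold at its brightest probe) fell (adjusted p = 0.0867 for the set). Cytochrome P450 genes gave 1 rise among 6 (adjusted p = 0.155), zinc finger and NAC factors 1 among 10 (0.29; mean 0.41, median -0.02), and histones 0 calls among 14 (0.681).

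Some probes with no description also had large pooled changes. AK321420 rose at least 403-fold (adjusted p = 0.00208), measured on 1 of 4 wild-type arrays, in line 1-30, and on all 4 knockdown arrays, and BF052115 rose by 6.45 on the log2 scale (SE 0.43, adjusted p = 0.00208; 3 of 4 wild-type arrays measured it). AW223100 fell at least 68.7-fold (adjusted p = 0.000998) and was well above background on all 4 wild-type and 0 knockdown arrays, and BI924590 fell at least 37.9-fold (adjusted p = 0.00723), measured on no knockdown array of line 1-10.

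A hypothesis from the ribosomal list is that transcripts of plastid ribosomal proteins may be lower than those of other ribosomal proteins in knockdown fruit. The 8 members annotated as plastid proteins had a mean of -0.79 (3 fell, adjusted p = 0.000194, and 0.11 with an estimated correlation) and the other 62 a mean of -0.17 (0 called, adjusted p = 0.00933, and 0.501 with an estimated correlation). The difference of the means was -0.62, and -0.58 and -0.66 within lines 1-10 and 1-30, but it was found and tested on the same data.

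Large differences between the lines were shared by both genotypes. As to a mislabelled line, all 4 knockdown arrays lay on their own line's side (1.71 and 1.66 against -1.19 and -1.21). Differences shared by both genotypes largely fix that outcome, so it is no separate test of mislabelling. A variant of the sequence under a single probe could give such differences and stays open. Of 151 other probes of the same genes 80 (53.0%) had a difference of the same direction and at least 50% of the size. In 37 of 93 genes no other probe did. That share covers called genes of every size. It was lower for genes with a wild-type difference beyond 5 on the log2 scale, most of which had no other probe in agreement. A slide effect as the whole cause was argued against, since each slide held both lines. On each, the knockdown siblings differed in the same direction, by a mean of 2.90 on slide 1 and 2.88 on slide 2. Their fold changes took no part in choosing these probes, but their spread did, through the shared variance. The choice may thus have brought the 2 means closer. The test written beforehand fell between its 2 outcomes, with the same sign on both slides for 271 of 343 probes (79.0%). All 343 were called with the slide as a block, which the balanced design largely fixes. A biological difference between the progenies, such as in background or transgene site, was not tested.

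As to the size of the pooled count, 2 of 35 splits of the arrays into 4 and 4 gave as many calls, so this count does not exclude chance. The real split gave 1872 without a line term. The highest other, the split by slide, gave 2369, which points to a structure of the samples. Of the 35, 18 splits put 2 arrays of each slide on each side, as the real one does. Among these the real one was the highest and the split by line came next with 351. With the slide as a block, fitted for these 18 splits alone, the real one gave 3186 and the highest other 393. Array brightness as the whole cause was argued against, since 1971 of 2147 probes were also called after quantile normalisation, though normexp left 817. Detection went with genotype, however. Probes well above background were 66.6% and 63.6% on the knockdown arrays of slide 1, against 60.9% and 62.3% on its wild-type arrays. On slide 2 they were 69.7% and 68.6% against 65.5% and 64.7%. Among probes well above background on all arrays 1960 were called, 53.1% of them higher, against 59.7% as reported. Whether the difference in detection adds to the count was not tested. A slide effect as the whole cause was argued against too: over all tested probes the effects on the slides, which share no array, correlated at r = 0.685 (median -0.033 over the other balanced splits, highest 0.595 for the split by line), and the 157 probes called on slide 2 alone all had the same sign on slide 1; that all 2147 (100%) agreed decides nothing because they were chosen for it. Each slide held an array of every group, so an effect equal on all arrays of a slide cancels from the knockdown contrast. Each group also had the same position on both slides, so the correlation between slides cannot tell position from genotype. An effect of the knockdown on many transcripts stays a hypothesis.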
